A study of Pyrus pyrifolia with 6 samples.

How the data were processed

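RNA was sequenced from the fruit skin of 'Cuiguan', a semi-russet sand pear (Pyrus pyrifolia), grown in an orchard on 7-year-old trees. Fruitlets of one group were bagged, first at 20 and again at 40 days after full bloom, and fruits of the other group stayed uncovered. All fruits were sampled 115 days after full bloom. Each group had 3 biological replicates per the labels. RNA came from a CTAB extraction, and libraries were made with a kit for which the labels name no strand marking, so overlapping and antisense genes cannot be separated.

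The submitters' processing notes name HISAT2. Its version, the counting tool, the genome build and the annotation are not given in the sources used here. The authors deposited 1 table with raw counts per gene and library, per the file headers. The same table holds FPKM values that the authors scaled to library totals between 2.48% and 9.33% above the count totals, and these were used only for that check. The authors also deposited a mean normalized signal per group, a log2 fold change, a p-value and an adjusted p-value for each gene, per the file headers, without naming a tool. Gene descriptions, Swiss-Prot matches and protein family names were taken from the table. Descriptions stop at 255 characters, a length reached by 4003 of 43727 genes (9.15%), so some list members and families may have been missed. A further 5 genes were not analysed here.

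Bagged skin was compared with unbagged skin on the deposited counts with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, libraries were scaled by TMM, and the robust quasi-likelihood test was followed by Benjamini-Hochberg adjustment with a threshold of 0.05. Of the 43727 genes, 10452 had no count in any library and 23934 were tested. Fold changes are log2 ratios of bagged over unbagged skin, and levels are counts scaled to library size (CPM, mean ± SD). Totals ran from 12534410 to 13443206 counts per library, and the 10 most abundant genes took 4.77% to 5.98% of them. The biological coefficient of variation was 23.2%. A level under 3 counts over a group was treated as a floor, and floors cover counting error only. Intervals of list medians come from 10000 bootstrap draws over the members and cover the spread among them.

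The 20 gene lists, the test, the alternatives and the rule for named genes were fixed before the data were examined. Lists were drawn by words in the gene descriptions and tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 20 lists. They cover suberin, monolignols, laccases and peroxidases, cuticle, photosynthesis, flavonoids, light and clock, secondary wall, wall loosening, ethylene, abscisic acid, auxin, heat shock, defence, sugar and flesh, vascular tissue, cell cycle, ribosome, MYB, and NAC or WRKY factors. Named genes passed the threshold, had groups that did not overlap, reached a mean of 5 CPM in the higher group and lay above the floor of 3 counts in both. The rule took the 4 largest and 4 smallest log2 fold changes, 2 members of each of the first 7 lists and 1 of each other list. A list without such a member gave its most abundant one.

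Alternatives were other scalings, other filters, limma-voom, DESeq2 1.42.0, a fold threshold, the replicate number as a block, each library left out in turn, camera with an estimated correlation, and fry. DESeq2 counts of list members cover those tested in edgeR unless stated otherwise. On counts simulated for bagged against unbagged skin (23934 genes), edgeR recovered 52% of genes changed 2-fold, 86% at 4-fold, 94% at 8-fold and 96% at 16-fold, and 19 of its 183 calls were unchanged genes (10.4%). DESeq2 recovered 60%, 94%, 98% and 100% of the same genes, and 57 of its 233 calls were unchanged (24.5%). The changed genes were drawn among those with a mean of at least 1 CPM, so recovery of rarer genes was not tested. In simulated lists the 1 changed list was called and 0 of 19 unchanged lists were. Simulated genes varied independently, while the estimated correlation was 0.386 in the suberin list and 0.12 in the photosynthesis list. The simulation thus does not test list calls under such correlation. Protein families were compared by Fisher's exact test, one-sided, among the 16854 tested genes with a readable family number.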

Results

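Gene expression was measured by RNA-seq in the skin of bagged and unbagged 'Cuiguan' pear fruit, with 3 libraries per group and 12534410 to 13443206 counts in each. The series addresses the partial russeting of this fruit, in which cork replaces part of the smooth skin. The comparison asked which genes differ in skin that developed inside bags.

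In bagged skin 28 of 63 cuticle genes rose, and 9 of 22 genes for suberin, the polyester of cork, fell while 3 rose. ECERIFERUM 1 (gene30160), an enzyme of wax alkane synthesis, had 0.0996 ± 0.0411 CPM in unbagged and 13.9 ± 3.52 CPM in bagged skin (SD, n = 3 each). CYP86B1 (gene4552), which hydroxylates very-long-chain suberin acids, fell from 26.6 ± 5.18 to 3.56 ± 1.84 CPM (SD, n = 3 each), while its more abundant copy gene6685 rose from 62.7 ± 12.8 to 134 ± 21.8 CPM (SD, n = 3 each). In all, 313 of 23934 genes passed the threshold of the edgeR test, 154 higher and 159 lower in bagged skin, and 292 of them changed by at least 1 on the log2 scale (145 higher, 147 lower). Rises of at least 16-fold were found for 83 genes and falls of that size for 12. The groups did not overlap in any of the 313 genes, nor in 18.2% of all tested genes, where chance gives 10%. DESeq2 called 852 genes, 311 of the 313 among them, and leaving out 1 library gave 153 to 269. The count was 159, 154 and 205 without unbagged replicates 1, 2 and 3, and 153 without bagged replicate 1.

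The 4 largest rises under the naming rule were in GDSL esterase/lipases, ECERIFERUM 1 and HOTHEAD. In the order below they rest on 13, 9, 4 and 17 counts over the unbagged libraries, so their sizes are uncertain. Some genes under the floor, which were not ranked, had larger estimates, such as gene5397 (8.99, at 0.0247 CPM in unbagged skin). LTL1 (gene39828, chromosome 4, 996275 to 998103), a GDSL esterase/lipase, rose by a log2 fold change of 7.51 (SE 0.19, edgeR adjusted p = 3.7e-06). A second GDSL esterase/lipase matching At5g33370 (gene27203, chromosome 12, 18499029 to 18501076) rose by 7.21 (SE 0.42, edgeR adjusted p = 0.000238). ECERIFERUM 1 (gene30160, chromosome 7, 5200989 to 5207303) rose by 6.99 (SE 0.38) and HOTHEAD (gene25700, chromosome 4, 16032258 to 16037916) by 6.98 (SE 0.32). The genome build behind these positions is not given in the sources used here. LTL1, ECERIFERUM 1 and several genes below have neighbours with the same Swiss-Prot match, so any sharing of reads between copies leaves their values uncertain.

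The 4 largest falls under the naming rule followed. Some genes below its 5 CPM minimum had falls of that size, such as the disease resistance homolog RGA1 (gene6940, log2 fold change -5.04), named after its values were seen. The bagged level of gene6940, 0.0253 CPM, lay under the floor of 3 counts, so the size of that fall is uncertain. Abscisic stress-ripening protein 1 (gene24588, chromosome 10, 4203878 to 4218647) went from 84.4 ± 14.8 to 2.5 ± 1.39 CPM (SD, n = 3 each), a log2 fold change of -5.06 (SE 0.36, edgeR adjusted p = 0.0013). Its neighbour gene24592, of the same protein family, fell by 4.77. A glutathione S-transferase (gene26514, chromosome 4) fell by 4.3, and CYP82A3 (gene1599, chromosome 15) by 4.95 (edgeR adjusted p = 0.0454). The CYP82A3 call was lost without any one of 5 libraries, with adjusted p from 0.0752 to 0.201.

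Cuticle genes rose as a group. Of 63 tested members 28 rose and 3 fell (33 and 7 adjusted over the list alone), with a median log2 fold change of 1.10. The list took 0.128% ± 0.00469 of counts in unbagged and 0.47% ± 0.0277 in bagged skin (SD, n = 3 each). Of that gain 81.7% came from 2 lipid-transfer protein genes, gene38249 and gene20898, and the other 61 members took 0.117% ± 0.00549 and 0.179% ± 0.00892 (SD, n = 3 each). Its camera adjusted p was 6.82e-18 (limma), and adjusted p = 0.0896 with an estimated correlation. CYP86A22 (gene23333, chromosome 6), a fatty acid hydroxylase, rose from 1.22 ± 1.15 to 141 ± 12 CPM (SD, n = 3 each). 3-ketoacyl-CoA synthase 10 (gene10410), which elongates fatty acids, rose by 5.32 and the lipid-transfer protein gene38249 by 4.59. The 3 members that fell were both copies of 3-ketoacyl-CoA synthase 4 (gene26182 and gene34030) and fatty acyl-CoA reductase 3 (gene31296), and 0 members fell in edgeR without any one of 5 libraries.

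Suberin genes moved the other way. Of 22 tested members 9 fell and 3 rose (15 and 3 adjusted over the list alone), with a median of -2.11, and camera gave an adjusted p of 7.12e-08 (limma). That call was lost at adjusted p = 0.52 with an estimated correlation. The list took 0.0415% ± 0.00967 of counts in unbagged and 0.0352% ± 0.000894 in bagged skin (SD, n = 3 each), a gap smaller than the SD in unbagged skin. CYP86B1 (gene4552, chromosome 16) fell by 2.89 and the transporter ABCG6 (gene36556, chromosome 1) fell by 2.77, a call lost without any of 4 libraries (edgeR adjusted p from 0.0607 to 0.134). CYP86A1 (gene22741), glycerol-3-phosphate acyltransferase 5 (gene3597), both ABCG20 copies and both omega-hydroxypalmitate O-feruloyl transferases also fell. The CYP86B1 copy gene6685 rose by 1.09, and the copies summed had 89.2 ± 17.1 and 137 ± 20.3 CPM (SD, n = 3 each, edgeR adjusted p = 0.164). Rises were also found for an alcohol-forming fatty acyl-CoA reductase (gene14546), by 2.69, and for ABCG11 (gene30928), known from cuticular lipid export, from 0.0737 ± 0.0735 to 3.02 ± 0.302 CPM (SD, n = 3 each). Falls numbered 2 without unbagged replicate 1, 2 without unbagged replicate 2, 5 without bagged replicate 1 and 4 without bagged replicate 2.

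**Figure D1:**
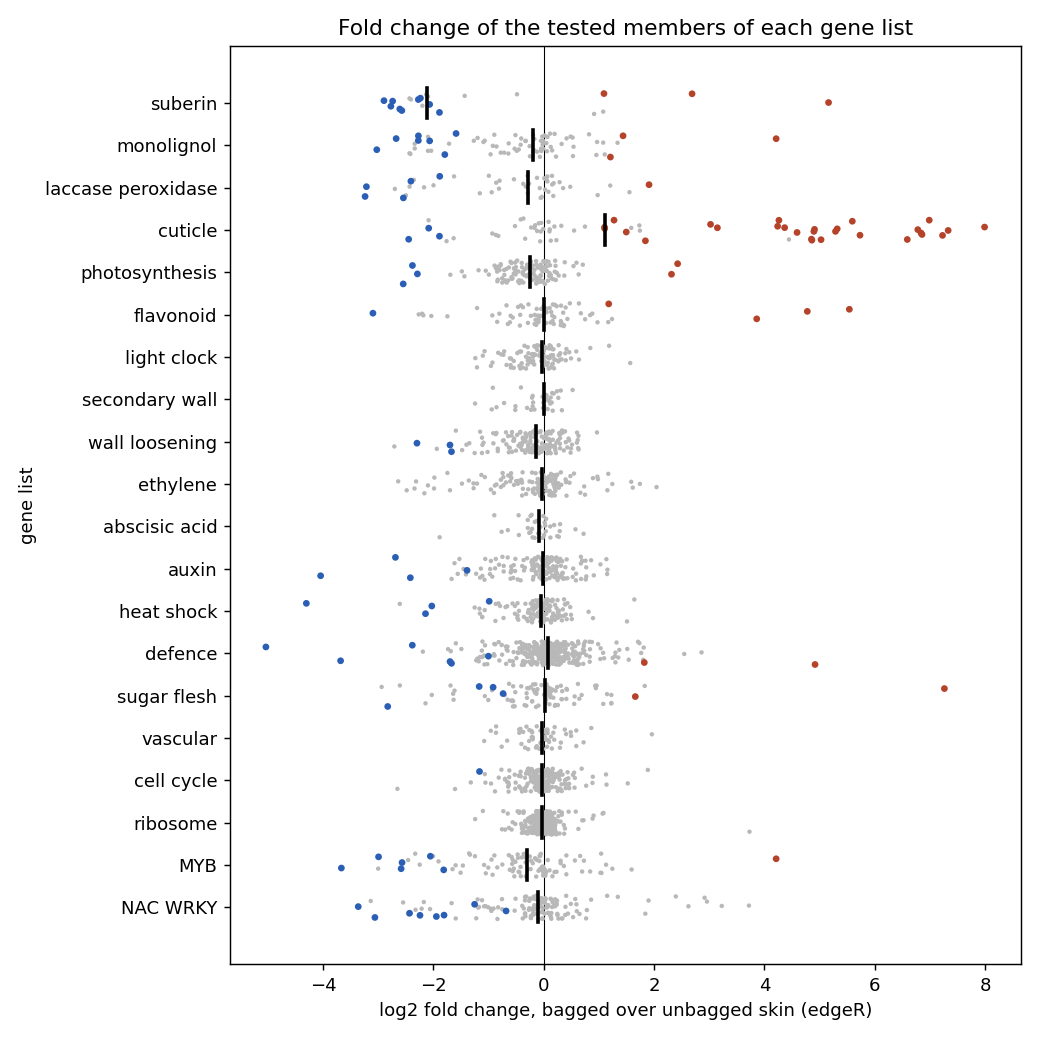
Each point is 1 tested gene at its log2 fold change, bagged over unbagged skin (horizontal axis, edgeR), by gene list (vertical axis, points spread at random within a list). Red points passed the threshold as higher, blue as lower, grey points did not pass, and black bars are list medians, 1.10 for cuticle and -2.11 for suberin.

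Lignin-related genes were lower in part. Of 76 monolignol members 7 fell and 3 rose (18 and 5 adjusted over the list alone), with a camera adjusted p of 0.000237 (limma) and adjusted p = 0.52 with an estimated correlation. CYP84A1 (gene31267, on an unplaced scaffold), the ferulate 5-hydroxylase, fell by 3.03, and the falls included the feruloyl transferases shared with the suberin list. Monolignol falls numbered 2 without unbagged replicate 1, 2 without unbagged replicate 2 and 4 without bagged replicate 1. Caffeoylshikimate esterase (gene36949, chromosome 7) rose from 2.68 ± 0.355 to 49.9 ± 5.3 CPM (SD, n = 3 each). Of 45 laccase, peroxidase and dirigent genes 5 fell and 1 rose (10 and 1 adjusted over the list alone), with a camera adjusted p of 0.000691 (limma) and adjusted p = 0.545 with an estimated correlation. Peroxidase 20 (gene20190, chromosome 6) fell by 3.24 and Peroxidase 47 (gene26165, chromosome 11) fell by 3.21. The Peroxidase 20 call was lost without any of 4 libraries (edgeR adjusted p from 0.115 to 0.133), and falls on this list numbered 2 without unbagged replicate 1, 2 without unbagged replicate 2 and 3 without unbagged replicate 3. Rises on this list numbered 0 in edgeR without any one of 5 libraries and 1 without bagged replicate 2.

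**Figure D2:**
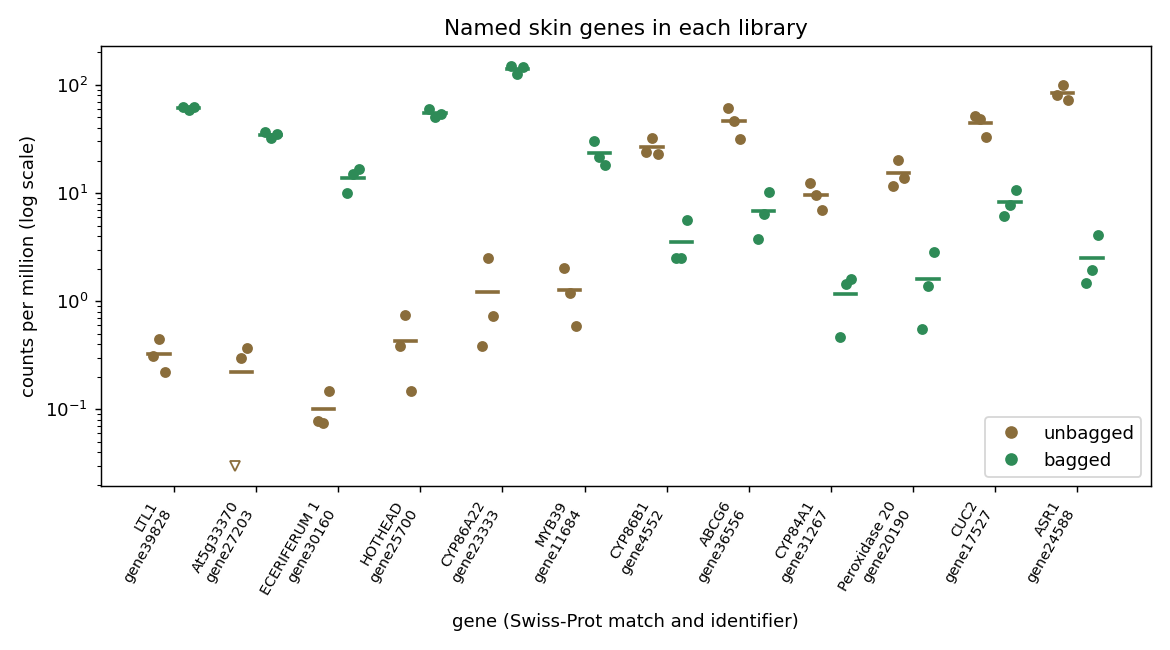
CPM (counts scaled to library size, vertical axis, log scale) of 12 named genes (horizontal axis) in each library, with bars at group means and an open triangle for a library with a count of 0. The 3 bagged libraries lie above the 3 unbagged ones in the first 6 genes, LTL1 at 61.1 against 0.325 CPM, and below them in the other 6.

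Photosynthesis genes were slightly lower as a list, with a median of -0.24, a camera adjusted p of 2.35e-06 (limma) and adjusted p = 0.52 with an estimated correlation. Of 130 members 2 rose and 3 fell (2 and 5 adjusted over the list alone). The 5 that passed carry a plastocyanin-like domain or are blue copper proteins, which are not part of the photosynthetic apparatus. They include gene80 (chromosome 5, log2 fold change 2.43) and early nodulin-like protein 1 (gene14288, chromosome 2, -2.38). Without unbagged replicates 1, 2 and 3 and bagged replicates 1, 2 and 3 in turn, falls numbered 0, 0, 0, 1, 1 and 2 in edgeR and rises 0, 1, 1, 0, 0 and 0. Without such members, a choice made after the data were seen, 0 of 110 genes passed in edgeR while the camera adjusted p was 1.4e-06 (limma), and adjusted p = 0.552 with an estimated correlation.

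Flavonoid genes split, with 4 rises and 1 fall among 72 members (6 and 6 adjusted over the list alone) and a camera adjusted p of 0.783 (limma). Flavonoid rises numbered 2 without unbagged replicate 3, and falls 2 without bagged replicate 2 or bagged replicate 3. A flavonoid 3-O-glucosyltransferase (gene37212, on an unplaced scaffold) rose by 5.54 and flavonol synthase (gene33758, chromosome 8) by 4.78. Among 112 light and clock genes 0 passed in edgeR, over all genes or adjusted over the list alone, with 16 at an unadjusted p under 0.05 and 3 in DESeq2 (4 of the 127 that DESeq2 tested). In edgeR 1 fell without unbagged replicate 2, and 1 of 148 fell with no filter. IAA27 (gene29841, chromosome 2), on that list through its description as a phytochrome-associated protein, had 1613 ± 110 CPM in unbagged and 1591 ± 180 CPM in bagged skin (SD, n = 3 each).

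Transcription factors were lower in part. Of 96 MYB members 6 fell and 1 rose (16 and 4 adjusted over the list alone), with a camera adjusted p of 1.55e-05 (limma) and adjusted p = 0.0896 with an estimated correlation. MYB39 (gene11684, chromosome 17) rose from 1.26 ± 0.717 to 23.5 ± 6.43 CPM (SD, n = 3 each), while both MYB44 copies (gene11737 and gene17879) fell. MYB falls numbered 1 without unbagged replicate 1, 0 without unbagged replicate 2, 1 without bagged replicate 1 and 3 without bagged replicate 2. MYB rises numbered 2 without bagged replicate 2 and 1 without any other library. Of 135 NAC or WRKY members 8 fell and 0 rose in edgeR (13 and 0 adjusted over the list alone, 14 and 0 in DESeq2), with 28 at an unadjusted p under 0.05. Over the 161 members that DESeq2 tested 14 fell and 1 rose, and without bagged replicate 2 edgeR gave 6 falls and 1 rise. Their camera adjusted p was 0.00389 (limma), and adjusted p = 0.603 with an estimated correlation. It was 0.079 without unbagged replicate 1 and 0.0703 without bagged replicate 1, where 4 and 3 members fell, and 5 fell without unbagged replicate 2, unbagged replicate 3 or bagged replicate 3. CUP-SHAPED COTYLEDON 2 (gene17527, chromosome 15), a NAC regulator of organ boundaries, fell by 2.43.

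The remaining lists did not pass the list test, although wall loosening passed without unbagged replicate 1 (camera adjusted p = 0.000858, limma) or bagged replicate 2 (0.00244), ethylene without bagged replicate 2 (0.0141), defence without bagged replicate 1 (0.00519) and ribosome without bagged replicate 3 (0.0264). The ribosome list was higher in bagged skin there and lower with all libraries. In wall loosening 3 of 156 fell (6 fell and 2 rose adjusted over the list alone), glucan endo-1,3-beta-glucosidase 7 (gene12000, chromosome 3) by 1.7. The falls of gene12000 and of glucan endo-1,3-beta-glucosidase 14 (gene38985) are counted again in defence, which shares 41 tested genes with this list. The remaining fall was pectinesterase 29 (gene23010). In defence 2 of 361 rose and 6 fell (3 and 6 adjusted over the list alone), and the allergen Pru ar 1 (gene37651, chromosome 16) rose by 4.92. In sugar and flesh 2 of 94 rose and 4 fell (4 and 5 adjusted over the list alone), with polyol transporter 5 (gene23840, chromosome 10) down by a log2 fold change of -2.83. In auxin 4 of 158 fell (4 fell and 1 rose adjusted over the list alone), among them the SAUR-type gene29504 (chromosome 7, -4.04) and 2 glutathione S-transferases. In heat shock 4 of 138 fell (5 fell and 1 rose adjusted over the list alone), among them gene26514, a glutathione S-transferase by its match. In cell cycle 1 of 192 fell (1 adjusted over the list alone), the HMG-Y-related gene27901 (chromosome 17, -1.18). Without unbagged replicates 1, 2 and 3 and bagged replicates 1, 2 and 3 in turn, edgeR falls numbered 1, 1, 3, 0, 3 and 1 in wall loosening, 1, 1, 3, 0, 2 and 1 in defence, and 1, 1, 2, 0, 1 and 1 in sugar and flesh. They numbered 2, 1, 3, 1, 1 and 2 in auxin, 1, 2, 2, 2, 4 and 2 in heat shock and 0, 0, 0, 0, 1 and 0 in cell cycle. Rises numbered 2, 1, 2, 1, 1 and 1 in defence and 1, 1, 1, 0, 2 and 3 in sugar and flesh. Without bagged replicate 2, 1 gene rose in each of wall loosening, auxin and cell cycle. The edgeR calls of gene31267 and gene12000 were each lost without either of 2 libraries, gene33758 without 1, gene23840 without 3, gene80 without 4, and gene14288 and gene27901 without 5.

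No member passed in edgeR, over all genes or adjusted over the list alone, in 5 further lists. Ethylene had 27 of 126 at an unadjusted p under 0.05 and 11 in DESeq2 (12 of the 147 that DESeq2 tested), abscisic acid 7 of 37 and 1, and secondary wall 4 of 38 and 1. Vascular genes had 6 of 60 and 1, and ribosomal proteins 10 of 289 and 2. With 1 library left out, edgeR called 1 ethylene gene higher without unbagged replicate 3, 1 lower without bagged replicate 2 and 1 lower without bagged replicate 3, and 1 secondary wall gene lower without bagged replicate 2. Their most abundant members had log2 fold changes of 0.00 for RAP2-2 (gene9415), -0.29 for PYL9 (gene29796), 0.12 for chitinase-like protein 1 (gene32273), 0.04 for 24-methylenesterol C-methyltransferase 2 (gene2836) and 0.14 for ribosomal protein L3 (gene33334). Median and test differed in sign for flavonoid, sugar and flesh, and secondary wall.

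Of the 20 lists, 7 passed camera at the preset correlation, 0 with an estimated one, 2 in the directional fry test and 18 in the mixed one, which asks only whether members change in either direction.

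The authors' deposited table holds 855 genes at their adjusted p under 0.05, 403 higher and 452 lower. All 852 genes of the DESeq2 refit are among them, and log2 fold changes of that refit differed from the authors' deposited table by at most 0.00024 over 32095 genes.

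The first principal component, 59% of the variance, separated the groups, with scores from -32.3 to -29 in unbagged and 25.6 to 35.6 in bagged libraries. The second, 16.5%, set bagged replicate 2 (-31.9) apart from the other bagged libraries (14 and 17.7). Without that library 269 genes passed in edgeR, 197 of them among the 313.

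**Figure D3:**
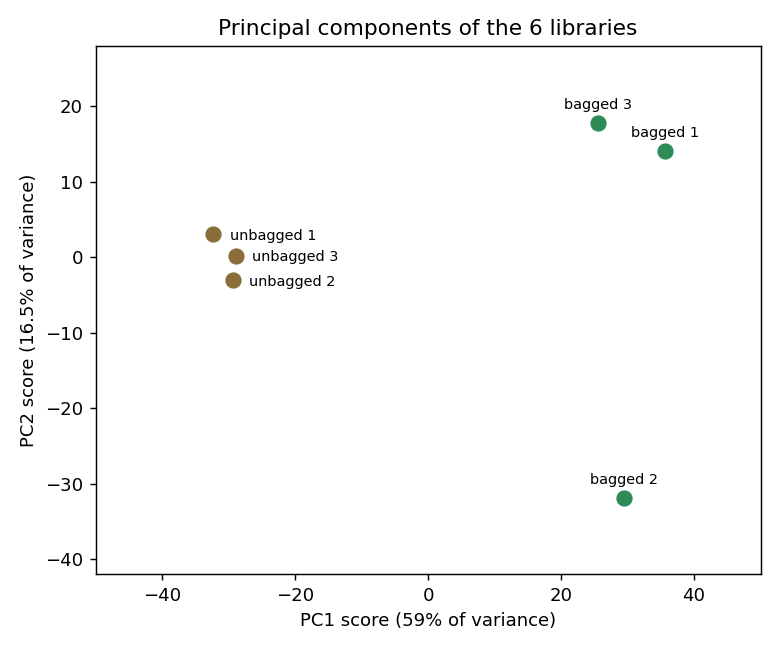
Scores of the 6 libraries on the first (horizontal axis, 59% of variance) and second (vertical axis, 16.5%) principal components of the 500 most variable genes, in log2 CPM. Bagged libraries are green and unbagged ones brown, and bagged replicate 2 lies at -31.9 on the second component.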

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

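Tests chosen after the data were seen were DESeq2 without independent filtering, edgeR without robust estimation and the photosynthesis list without plastocyanin-like members. The other scalings gave 310 to 330 genes, limma-voom 295, no filter 384 and edgeR without robust estimation 320, and no called gene changed sign under any setting. DESeq2 gave 852 genes (400 higher, 452 lower, 644 at a log2 fold change of at least 1), and 832 (389, 443 and 607) on the edgeR genes without independent filtering. The 5 CPM filter tested fewer genes, 17209, and gave 201 (101, 100 and 186). The test against a fold threshold gave 117 (93, 24 and 117), which its stricter null explains. Leaving out 1 library gave 153 to 269 genes, 102 to 167 higher, 41 to 131 lower and 153 to 251 at a log2 fold change of at least 1, with fewer samples in each.

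With the replicate number as a block 137 genes passed (94 higher, 43 lower, 133 at a log2 fold change of at least 1). Deviations of libraries with the same number correlated at -0.048, 0.00399 and -0.0171, so no broad signal shared by number was seen. That cannot exclude that the numbers mark a shared tree or day, which the labels do not state. The block brought wall loosening past the threshold (adjusted p = 0.0298 in limma) and changed no other call of the list test, while the members that fell numbered 0 for suberin (9 without the block) and those that rose 20 for cuticle (28 without it). Against a log2 fold change of 1, suberin falls numbered 1.

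With an estimated correlation the camera adjusted p was 0.52 for suberin, monolignol and photosynthesis, 0.545 for laccases and peroxidases, 0.0896 for cuticle and MYB, and 0.603 for NAC or WRKY. Directional fry kept the calls of cuticle (adjusted p = 0.000949) and MYB (adjusted p = 0.0292). It gave 0.214 for suberin, 0.238 for monolignol, 0.249 for laccases and peroxidases and for photosynthesis, and 0.298 for NAC or WRKY. Mixed fry brought 11 lists past the threshold, with 0.00031 for flavonoid, defence, and sugar and flesh, 0.00114 for wall loosening and heat shock, 0.00286 for light and clock, 0.0344 for ethylene, 0.0461 for abscisic acid, 0.00263 for auxin, 0.00955 for vascular and 0.00177 for cell cycle. The cause of these differences was not tested.

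Leaving out 1 library, list adjusted p ran from 0.342 to 0.888 for flavonoid, 0.513 to 0.932 for secondary wall, 0.000858 to 0.486 for wall loosening, 0.0141 to 0.292 for ethylene, 0.232 to 0.733 for auxin, 0.00519 to 0.562 for defence, 0.436 to 0.962 for sugar and flesh, 0.723 to 0.921 for cell cycle, 0.0264 to 0.591 for ribosome and 0.000191 to 0.079 for NAC or WRKY. Direction turned for flavonoid, secondary wall, auxin, sugar and flesh, cell cycle and ribosome. Log2 fold changes that turned ran from -0.12 to 0.0375 for IAA27 (gene29841), -0.0200 to 0.23 for chitinase-like protein 1 (gene32273), -0.0606 to 0.0701 for RAP2-2 (gene9415) and -0.0225 to 0.159 for 24-methylenesterol C-methyltransferase 2 (gene2836).

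Library size alone turned the auxin list (adjusted p = 0.948) and gave RAP2-2 (gene9415) a log2 fold change of -0.0379. Of 541 pairs of a named gene and a setting, 472 kept direction and side of the threshold, 59 lost the call and 10 turned direction in genes that never passed. Of 26 called named genes 13 passed under every setting, and 11 were lost under the block. The alternatives for a table with only FPKM were not run, since counts were deposited. Depth limits genes near the floor: 30 called genes had a group under 3 counts.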

Other observations

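Among tests reported here, the comparison of flesh and skin lists, the summed suberin entries, the position of bagged replicate 2 between the groups, its count of raised genes, the protein families and the gene neighbours were chosen after the result was seen. GDSL esterase/lipases held 16 of the 129 higher genes with a family number where 0.329 were expected by chance (Fisher's exact test, adjusted p = 1.33e-20). They also held 6 of the 130 lower ones, where 0.332 were expected (Fisher's exact test, adjusted p = 0.000567). LTL1 (gene39828), 3 APG copies and EXL3 (gene2861) rose, while both At2g23540 copies fell. The transferase family that includes the cutin enzyme DCR held 8 higher genes (adjusted p = 2.06e-07) and 3 lower ones. The DCR copy gene32423 had 1.3 ± 0.312 and 73.4 ± 12 CPM (SD, n = 3 each). Another DCR copy, gene18204, did not pass, at 65 ± 5.33 and 64.3 ± 11.4 CPM (SD, n = 3 each, edgeR adjusted p = 0.98). BURP domain genes matching RD22 gave 3 rises (adjusted p = 0.00812), gene17517 from 4.46 ± 1.26 to 219 ± 31.4 CPM (SD, n = 3 each). Lower genes held 9 cytochromes P450 (adjusted p = 0.000567), with 2 among the higher genes, and 6 NAC genes (adjusted p = 0.00286, with 0 among the higher genes). CYP86A22 (gene23333), which rose by 6.84, has no readable family number and is missing from the P450 counts. Genes of 1 family are not independent, so these p are too small.

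Of the 313 called genes 35 had another gene called the same way within 5 genes on the sequence, against a median of 11 in 10000 random sets matched on level (permutation p = 1e-04, the smallest they can give).

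The rise of cuticle and fall of suberin genes was set against 3 explanations. Flesh that diluted every skin layer alike would move both lists the same way. Their medians lay 3.23 apart (log2), with intervals on opposite sides of 0 (0.11 to 3.02 and -2.41 to -1.43). That contrast restates the pattern, so it speaks only to even dilution and leaves a changed mix of skin layers open. The 94 sugar and flesh genes had a median of 0.032, inside the range of matched random lists (-0.0533 to 0.0641). How far these genes are confined to flesh was not tested, so their median cannot decide whether the amount of flesh differed. More epidermal cells would raise genes confined to the epidermis. The median of 24 epidermal identity genes was -0.0103 (95% interval -0.242 to 0.204, matched random lists -0.121 to 0.115), so the list as a set did not rise. It cannot decide the question, since how far its members, such as ALE2, DEK1 and WRKY44 matches, are confined to the epidermis was not tested. Of the 24 genes 3 rose, HDG2, ROC3 and the DCR copy gene32423, and 0 fell. The other DCR copies on the list, gene10233, gene18204 and gene19417, did not pass. Reads shared between near-identical copies would leave few rises once copies were summed, but 14 of 30 summed cuticle entries were higher. For the suberin part this explanation stays open, since 4 of 10 summed entries were lower and 1 higher. An effect of bagging itself also stays open, as untested.

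Bagged replicate 2 stood apart on the second component. Genes of rapid wound response lay 1.28 (log2, median of 49 genes) above the other bagged libraries in it. That is outside the range of random lists matched on level and scored for that library (-0.0925 to 0.115). A stress response in bagged replicate 2 would give such a shift. The gene list was written after other genes in that library had drawn attention, and leaves those out. Random lists do not allow for genes that move together, so their range may be too narrow. ZAT10 (gene6423) had 288.8 CPM there against 16.9 and 11.7. Set against the rest of their own groups, bagged replicates 1 and 3 lay at -0.776 and -0.267, with bagged replicate 2 in that rest, and unbagged replicates 1, 2 and 3 at 0.141, 0.0254 and -0.0615. That range was scored for bagged replicate 2 alone, and its own shift lowers the values of bagged replicates 1 and 3. Whether such a shift was particular to bagged replicate 2 cannot be told from these values, though its shift was the largest. For lower depth the test set beforehand left the question open, since totals differed so little that thinning changed nearly nothing (16.5% of the variance on the component after it). The count of raised genes argues against it. Among 17173 genes with a mean of at least 5 CPM, 163 lay over 4-fold above the other bagged libraries (21 below) at a total of 12534410, while unbagged replicate 1, at 12670912, had 39 such genes above the other unbagged libraries (48 below). For a mislabelled unbagged library the test set beforehand left the question open: 79.5% of 264 genes lay on the bagged side of the midpoint, a reading of the bagged side fixed only afterwards, between the bounds of 50% and 90%. These 264 are the genes called without it, 269 in all, that were also tested with all 6 libraries. By position between the groups it lay at 0.873, where unbagged libraries held out likewise lay at 0 to 0.0927 and bagged replicate 3 at 0.788, which argues against it.

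With 3 against 3 samples there are 10 splits, too few for a share under 0.05. The real split gave 313 genes and the highest other 0, and 292 against 0 at a log2 fold change of at least 1 (1 of the 10 splits reached each). For lists, 2 of the 10 splits reached the real value of 7, and the split of unbagged 1, unbagged 2 and bagged 2 against the rest gave 9. Camera at the preset correlation thus called as many lists on a grouping that is not the treatment, and list calls here carry less weight than gene calls.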
